A study of Schizosaccharomyces pombe with 2 samples.

How the data were processed

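The series holds 2 two-channel Agilent arrays, 1 per biological replicate pair, each with RNA of the mga2Δ strain in one channel and of the control in the other. Per the labels' protocols, 400 ng of total RNA was amplified with oligo-dT primers and labelled with cyanine CTP, and spike-in RNAs were added before amplification. Spot intensity values were extracted with Agilent Feature Extraction 10.5.1.1 and protocol GE2_105_Dec08, per the file headers; Partek is also named in the submitters' processing notes, with no step given. The deposited scanner tables give median intensity of each spot and of its local background, intensities corrected and dye-normalized by the scanner software, and the log10 ratio of Cy5 over Cy3. The authors' deposited value table holds 1 log2 ratio per probe and array. Set against the scanner log ratios, it runs as mga2Δ over WT on both arrays and is centred on each array's mean, with medians of −0.078 and −0.115; its exact normalization is not given in the sources used here. Both arrays lay on the same slide and were scanned together, so no slide or scan batch could be tested.

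Median spot and background intensities were used in place of the mean spot intensities planned before the data were examined. Background was corrected with normexp (offset 50), and each array was normalized by loess with control spots and outlier spots at weight 0, in limma 3.58.1 under R 4.3.3. Spots called non-uniform or population outliers were left out (3.57% and 3.36% of gene spots), saturated spots would have been kept, and spots of a probe were averaged. The sign of array 2 was turned, so that both arrays give mga2Δ over WT. A probe was tested if at least 2 of its spots were well above background in 1 or both channels on each array, which left 4964 of 5057 probes, each of a different gene. Bounds for genes below background came from channel values after loess and Aquantile normalization. Probe names were matched to gene symbols through a RefSeq gene table of assembly ASM294v3, used for names and neighbours only: 5021 matched by locus tag, 3 by alias and 33 not at all.

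The ratio was tested per gene with lmFit and eBayes against 0, two-sided, with Benjamini-Hochberg adjustment at 0.05. A dye term would have left no residual degree of freedom, and the swap balances the dyes in the mean. The same fit with both arrays as Cy5 over Cy3 gave the dye-direction background. The 19 gene lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and adjusted over the lists. The latter form has only 1 residual degree of freedom, so hardly any list could pass it. The symbols taz1, peg1 and any1 were left out of their lists before values were seen, because they name other genes in this species. Genes named in the text are 8 fixed in advance (mga2, sre1, ole1, fas1, cut6, hem13, erg25 and erg31), the 10 most raised and 10 most lowered called genes with the same sign on both arrays, and up to 4 members of each list with the largest mean ratio in size. Further members of the fatty acid list, the markers ura4 and his3 and suc22 were named after their values were seen. A gene that the rule would name is not reported here. Design, gene lists and alternatives were fixed before the data were examined, except where the text says otherwise. Other tables were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

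The steps were tested on simulated spots for all 4964 genes, with a dye curve, background and gene spreads drawn from the fitted prior. In 21 runs with 200 changed genes, a median of 90% of genes changed 1.5-fold were called in the true direction (58% to 100%), and 100% of those changed 2-fold (98% to 100%). The first of these runs had failed the check set for it, a limit on false calls: 24.9% of its calls were false. The runs were therefore repeated and the limit replaced by the measured share. False calls made up a median of 7.35% of calls (2.73% to 24.9%), above the nominal rate, and 4.57% (1.52% to 8.7%) when the simulated prior was used in place of the estimated one. The estimated prior degrees of freedom ranged from 4.59 to 90.7 where 5.62 had been simulated. In 21 runs with the 1456 called genes changed by their measured ratios, false calls made up a median of 4.53% (2.31% to 6.84%). These runs take the fitted spread as true and do not test it.

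The alternatives tried were no background correction, normexp with offset 16, the scanner software's processed signals, median centring, scale normalization between arrays, all probes, probes above background in both channels, separate-channel analysis, the deposited ratios, an adjusted p of 0.10, eBayes with trend and robust settings, a 1.5-fold threshold, an estimated correlation and each array alone. Centring on spike-in RNAs and 2.81 prior degrees of freedom in place of 5.62 were added after seeing the data.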

Results

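Gene expression was compared between a fission yeast (Schizosaccharomyces pombe) strain lacking mga2 and its control strain, both grown in rich YES medium and held without oxygen for 1.5 h in an anaerobic chamber. Mga2 is a transcriptional activator of lipid genes, and the series title asks about lipid homeostasis and the activation of SREBPs, the sterol-responsive transcription factors. The deletion strain was ESY173 (mga2Δ below) and the control KGY425 (WT below). The sample labels call the control wild type, whereas the series design text describes both strains as also lacking sre1, the gene of the main fission yeast SREBP. The arrays bear on this point: the sre1 probe was not well above background in either strain on either array, which by itself does not settle whether the gene was deleted. No sample with oxygen was analysed here, so all values compare the strains without oxygen and none gives the response to its loss.

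RNA from 2 biological replicate pairs was hybridised to 2 Agilent arrays with the dyes swapped. On array 1 the mga2Δ RNA carried Cy5 and the WT RNA Cy3, and on array 2 the dyes were reversed. Each array held 15171 gene spots for 5057 probes, with 3 spots per probe. Median signals of gene spots on array 1 were 897.5 in Cy3 and 2322.5 in Cy5, against 18.5 and 61 at the negative control spots. On array 2 they were 858 and 1579, against 18 and 62. Between 96.8% and 98.6% of probes were well above background in each channel, and no spot was saturated. The number of arrays limits the precision: each mean below is over 2 arrays, each SD is between them, and the test had 1 residual degree of freedom per gene. Values below are log2 ratios of mga2Δ over WT, relative to the bulk of the genes on the array.

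The mga2 transcript fell in mga2Δ, with log2 ratios of −7.27 on array 1 and −6.13 on array 2 (mean −6.70 ± 0.81, SD, n = 2 arrays, limma adjusted p = 1.26e-05). The mga2 probe was well above background in WT on both arrays and in mga2Δ on neither, so the mga2Δ level has only a bound, and mga2 was at least 85.1-fold lower. That bound sets the mean WT signal against the lowest signal among probes well above background, or the probe's own where higher. The probes of ura4 and his3, nutritional markers often deleted in laboratory strains, were not well above background in either strain. The markers lys1, arg3, leu1 and ade6 had mean log2 ratios of −0.37, −0.33, −0.30 and −0.18, and leu1 passed the test (adjusted p = 0.0451). These calls depended on the setting. The leu1 ratio did not pass with processed signals (adjusted p = 0.0687), median centring (0.235) or spike-in centring (0.335). Both lys1 and arg3 passed in several other settings, such as with the deposited ratios (adjusted p = 0.00861 and 0.0249).

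Expression differed widely between the strains, and the larger changes were mostly rises. The most raised transcripts were shu1, a cell-surface haem uptake protein (5.78 ± 1.49), the stress gene ddr48 (5.40 ± 0.41), cmt2 (4.74 ± 0.07), eno102, an enolase (4.45 ± 0.51), hsp16, a small heat shock protein (4.42 ± 0.30), ssd2 (4.33 ± 0.51) and SPBC24C6.09c (4.25 ± 0.32), each as SD over 2 arrays. They were followed by str3, an iron-siderophore transporter family member (4.22 ± 1.68), SPCC737.04 (4.11 ± 0.14) and SPAPB1A11.03 (4.04 ± 0.41). WT signal of str3 was not well above background on either array, so str3 was at least 17.2-fold higher in mga2Δ. That of shu1 was well above background on both arrays but nearly as low (log2 6.48 and 6.06, against 6.29 and 5.84 for str3). The size of the shu1 ratio is therefore less certain. After mga2 itself, the most lowered transcripts were vht1, the biotin transporter (−2.54 ± 0.85), lcf1, a long-chain fatty acyl-CoA ligase (−2.47 ± 0.19), ptl2, a triacylglycerol lipase (−2.16 ± 0.14), izh3 (−2.16 ± 0.10) and SPAC3G6.05 (−2.11 ± 0.70). The list went on with spo6, a regulator of meiosis (−2.09 ± 0.09), the lipase ptl1 (−2.03 ± 0.18), tlc4 (−1.84 ± 0.015) and the acyl-CoA ligase lcf2 (−1.69 ± 0.09). Adjusted p-values of these 20 genes lay between 3.24e-06 for cmt2 and 0.00111 for str3.

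Of 4964 genes tested with limma, 915 were raised and 541 lowered in mga2Δ at a Benjamini-Hochberg adjusted p of 0.05, 29.3% of the genes tested, and 62.8% of the calls were rises. Ratios of at least 2-fold in the same direction on both arrays, a count that needs no test, were seen for 179 raised and 26 lowered genes (196 and 43 with the deposited ratios, 229 and 18 with spike-in centring). Log2 ratios of the arrays correlated across genes with Pearson's r of 0.913 and Spearman's rho of 0.783, where genes are not independent replicates. When both arrays were taken as Cy5 over Cy3, so that the strains cancelled, limma called 0 genes (0 at an unadjusted p under 0.05, against 2071 in the strain direction) and 0 genes reached 2-fold on both arrays. In that orientation strain differences enter the residual spread and leave the test little power. Sizes compare more directly: the mean was at least 0.5 in 725 genes in the strain direction and in 26 in the dye direction. The number of calls rested on a prior spread that 1 residual degree of freedom estimates poorly: with 2.81 prior degrees of freedom in place of 5.62, a setting chosen after seeing the data, 493 genes were raised and 176 lowered. Of the 92 named genes tested, 50 lost their call with median centring, in part at ratios about as large, such as Tf2-8 at 0.62, ste11 at 0.82, mei2 at 0.78, isp5 at 0.77, aat1 at −0.86, hem3 at −1.03 and osm1 at 0.59. The split also moved with the normalization and the centre of the ratios. It was 146 raised and 26 lowered with median centring, 886 and 812 with the scanner software's processed signals, and 750 and 1138 with the authors' deposited ratios. With ratios centred on the spike-in RNAs, chosen after seeing the data, it was 1832 and 195. Only this last setting changed the centre alone.

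**Figure D1:**
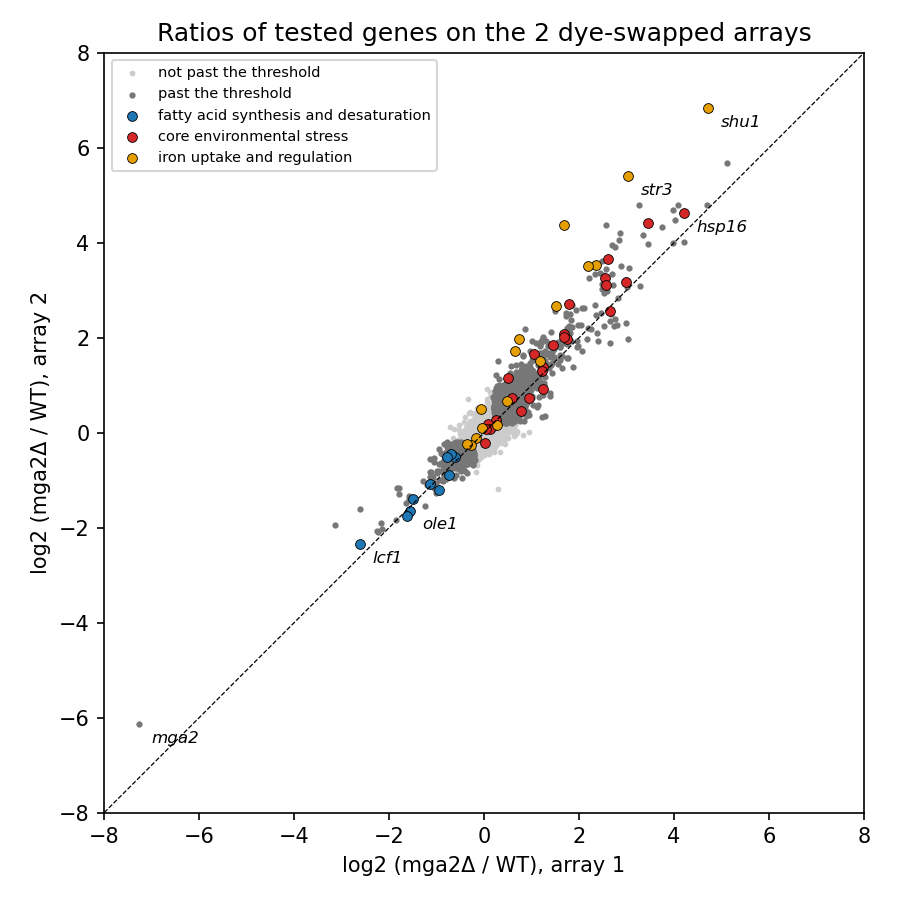
Log2 ratio of mga2Δ over WT on array 1 (x axis) against array 2 (y axis), 1 point per tested gene, with the members of 3 gene lists coloured and the dashed line marking equal ratios. Pearson's r across genes was 0.913, and the iron genes shu1 and str3 lay above the line, at 4.72 and 6.83 and at 3.03 and 5.40.

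Fatty acid synthesis and desaturation genes fell as a group. Of the 11 members tested, 10 were lowered and none was raised, with a list median of −1.08, and the counts adjusted over the list alone were the same. The acyl-CoA ligases lcf1 and lcf2 fell most, followed by ole1, the delta-9 fatty acid desaturase (−1.60 ± 0.05, n = 2 arrays, limma adjusted p = 5.92e-05), cut6, acetyl-CoA carboxylase (−1.44 ± 0.08, adjusted p = 9.01e-05), and fas1, the beta subunit of fatty acid synthase (−1.10 ± 0.04, adjusted p = 0.000271). Lowered too were acs1, acetyl-CoA synthetase (−1.08 ± 0.18), fas2, the alpha subunit of the synthase (−0.81 ± 0.11), and bpl1, biotin-protein ligase (−0.57 ± 0.18). The member that did not pass, lsd1 (0.17 ± 0.03), was listed as an older name of fas2 and now names a histone demethylase. The list lay below the other genes by the camera set test (adjusted p = 5.23e-08 over 19 lists, adjusted p = 0.646 with an estimated correlation). The ole1 call did not hold with median centring (−2.16, adjusted p = 0.101).

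Genes of glycerophospholipid and triacylglycerol synthesis were lowered in 9 and raised in 1 of 25 tested members (2 raised and 9 lowered when adjusted over the list alone). The acyltransferases ale1 (−0.73 ± 0.10), slc1 (−0.60 ± 0.06) and sct1 (−0.57 ± 0.02), which add fatty acids to the glycerol backbone, were lowered. The raised member was gpd1, glycerol-3-phosphate dehydrogenase (0.83 ± 0.45), which also belongs to the stress list. With median centring gpd1 stood at 0.34 and did not pass (adjusted p = 0.372), and neither did ale1, slc1 and sct1, whose ratios of −0.73, −0.65 and −0.57 stayed about as large. The camera adjusted p was 0.0223 (adjusted p = 0.646 with an estimated correlation), and the list median of −0.12 became 0.07 under spike-in centring. In sphingolipid synthesis, 3 members were lowered and 1 was raised of 10 (4 lowered and 2 raised over the list alone), led by tsc13, an enoyl reductase of very-long-chain fatty acid elongation (−1.44 ± 0.11). The others were scs7 (−0.44 ± 0.07) and lag1 (−0.34 ± 0.01), both lowered, and sur2 (0.53 ± 0.28), raised. With median centring these 3 did not pass, at ratios of −0.40, −0.37 and 0.56, and under spike-in centring scs7 (−0.25) and lag1 (−0.15) did not. The camera adjusted p for this list was 0.347.

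Ergosterol synthesis genes went both ways. Of 25 tested members 5 were raised and 4 lowered, the same when adjusted over the list alone, with a median of 0.00 and a camera adjusted p of 0.464. The raised members included erg32 (1.02 ± 0.29) and are2 (0.64 ± 0.34), and the lowered ones hmg1, HMG-CoA reductase (−0.92 ± 0.10), idi1 (−0.44 ± 0.29), erg31 (−0.37 ± 0.04, limma adjusted p = 0.0238, n = 2 arrays) and erg25 (−0.33 ± 0.002, adjusted p = 0.033). Under spike-in centring erg25, erg31 and idi1 no longer passed, and with median centring none of these 6 did (adjusted p from 0.0506 for hmg1 to 0.271 for idi1), at ratios of 1.01 for erg32, 0.63 for are2, −1.01 for hmg1, −0.53 for idi1, −0.33 for erg31 and −0.40 for erg25. Among 14 genes of SREBP processing and regulation, 7 were raised and 3 lowered (7 and 4 over the list alone, camera adjusted p = 0.607). Raised were cdc48 (0.94 ± 0.25), ubc4 (0.53 ± 0.12) and dsc3 (0.50 ± 0.04), and scp1, the sterol sensor of the pathway, was lowered (−0.50 ± 0.29). With median centring none of these 4 passed, with cdc48 at 0.49, ubc4 at 0.018, dsc3 at 0.43 and scp1 at −0.47, and scp1 did not pass under spike-in centring (adjusted p = 0.0732). Of 21 oxygen-requiring and haem synthesis enzymes, 7 were lowered and 3 raised (7 and 4 over the list alone, camera adjusted p = 0.0656). The haem synthesis genes hem1 (−1.48 ± 0.45) and hem3 (−0.96 ± 0.05) were lowered and osm1 (0.61 ± 0.07) was raised. The hem13 ratio of −0.30 ± 0.28 did not pass (adjusted p = 0.0985), but passed with processed signals (adjusted p = 0.0482), scale normalization (adjusted p = 0.0448) and the deposited ratios (adjusted p = 0.0487).

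**Figure D2:**
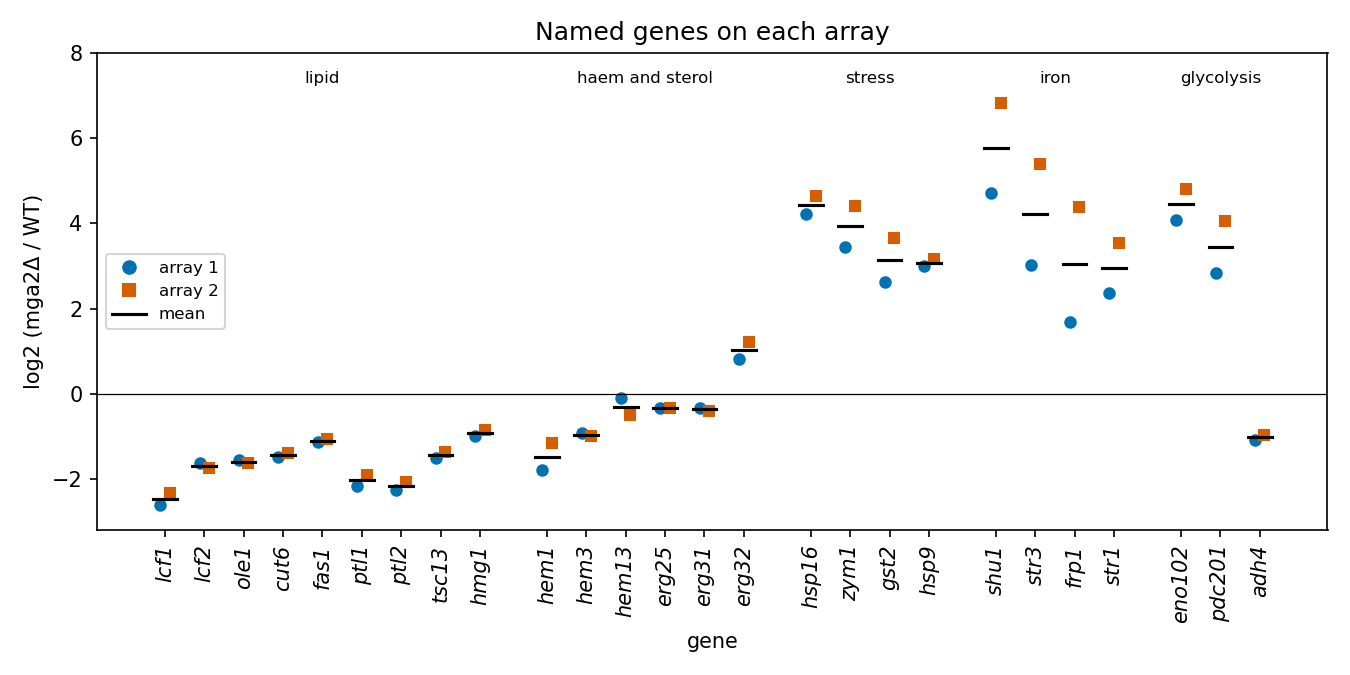
Log2 ratio of mga2Δ over WT (y axis) of named genes (x axis) on array 1 (circles) and array 2 (squares), with the mean as a bar. Fatty acid genes such as ole1 (−1.56 and −1.64) differed little between the arrays, whereas frp1 stood at 1.69 and 4.39.

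Core environmental stress genes rose as a group, with 20 of 25 members raised and none lowered (21 raised when adjusted over the list alone), a median of 1.36 and a camera adjusted p of 7.2e-13 (adjusted p = 0.646 with an estimated correlation). Besides hsp16, the largest rises were in zym1, a metallothionein (3.94 ± 0.69), gst2, a glutathione S-transferase (3.14 ± 0.73), and hsp9, a small heat shock protein (3.08 ± 0.12). Of 13 genes of ER chaperones and the unfolded protein response, 5 were raised and none lowered (6 raised over the list alone, camera adjusted p = 0.065), among them gas2 (1.37 ± 0.04), ero11 (0.77 ± 0.40), bip1 (0.57 ± 0.26) and cnx1 (0.42 ± 0.24). With median centring none of these 4 passed: gas2 stood at 0.74, ero11 at 0.69, bip1 at 0.14 and cnx1 at −0.069.

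Iron uptake genes were raised in 10 of 16 tested members and lowered in none (10 raised and 2 lowered over the list alone), with a median of 1.27 and a camera adjusted p of 0.00198 (adjusted p = 0.646 with an estimated correlation). The estimated correlation of the members was 0.75, far above the preset 0.01, so the camera adjusted p of 0.00198 is probably too small. After shu1 and str3 came frp1, a ferric reductase (3.04 ± 1.91, limma adjusted p = 0.00747, n = 2 arrays), and str1, a siderophore transporter (2.96 ± 0.83). Their size differed between the arrays, with the list median at 0.70 on array 1 and 1.62 on array 2, and frp1 at 1.69 and 4.39. With median centring frp1 (3.02, adjusted p = 0.13) and str3 (4.20, adjusted p = 0.0808) did not pass, though their ratios stayed as large.

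In glycolysis and fermentation, 4 of 19 members were raised and 1 was lowered (7 and 1 over the list alone, camera adjusted p = 0.261). Besides eno102, pdc201, a pyruvate decarboxylase, was raised (3.45 ± 0.86), and adh4, an alcohol dehydrogenase, was lowered (−1.02 ± 0.08). The pgk1 ratio of 0.48 ± 0.66 did not pass, but passed with scale normalization (adjusted p = 0.0223) and spike-in centring (adjusted p = 0.0387). The list median of 0.24 turned to −0.31 with median centring. Mitochondrial respiration genes mostly did not pass, with 2 raised and 1 lowered of 25 (0 and 0 over the list alone, camera adjusted p = 0.84). Named members were atp5 (0.36 ± 0.13), qcr6 (0.31 ± 0.07) and atp16 (−0.35 ± 0.09), while atp2 (0.29 ± 0.11) did not pass. These calls lay near the threshold: atp5 and qcr6 did not pass with median centring or the deposited ratios (qcr6 at 0.056 and 0.18), atp16 did not under median or spike-in centring (−0.16), and atp2 passed with scale normalization (adjusted p = 0.0338) and spike-in centring (adjusted p = 0.00807).

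Of 131 cytoplasmic ribosomal protein genes, 17 were lowered and none was raised (6 lowered over the list alone). Over all 4964 tested genes, 541 were lowered and 915 raised. The list median was −0.10, with a camera adjusted p of 8.71e-05 (adjusted p = 0.646 with an estimated correlation), and became 0.09 under spike-in centring and −0.67 with median centring. The members with the lowest ratios were rpl1603 (−0.65 ± 0.05), rpl4102 (−0.60 ± 0.19), rps2802 (−0.51 ± 0.11) and rpl3402 (−0.47 ± 0.01). None of these 4 passed with median centring, at −0.611, −0.685, −0.687 and −0.538 (limma adjusted p from 0.122 to 0.168). These genes have paralogs, and whether their probes separate the copies was not checked here. The list of G1/S transcription and histone genes had 9 raised and 1 lowered of 16 (9 and 1 over the list alone, camera adjusted p = 0.0277, adjusted p = 0.646 with an estimated correlation). The raised members were histone genes and suc22, a ribonucleotide reductase subunit, led by hhf2 (0.95 ± 0.04), hhf3 (0.86 ± 0.06), hhf1 (0.84 ± 0.02) and hht3 (0.79 ± 0.05), near-identical copies that are uncertain one by one. With median centring the list's adjusted p was 0.409 and none of these 4 passed, with hhf2 at 0.57, hhf3 at 0.33, hhf1 at 0.31 and hht3 at 0.41. Histone copies are not independent measurements, so the list's counts and its set test with a preset correlation may count the same rise several times. Only suc22 among the raised members was not a histone gene. All 6 Tf2 retrotransposon probes were raised (6 over the list alone, camera adjusted p = 0.00198, adjusted p = 0.646 with an estimated correlation), with Tf2-8 at 0.66 ± 0.23, Tf2-1 and Tf2-3 at 0.65, and Tf2-13 at 0.64. These elements are near-identical and count as 1 measurement, so the set test with a preset correlation, which takes them as nearly independent, says little here.

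Among 23 tested mating and meiosis genes, 9 were raised and 2 lowered (9 and 2 over the list alone, camera adjusted p = 0.065). Besides the lowered spo6, rec10, a component of meiotic chromosome axes (1.23 ± 0.09), ste11, the transcription factor of mating (0.79 ± 0.38), and mei2 (0.72 ± 0.57) were raised. Of 17 genes in the nitrogen and amino acid transport list, 6 were raised and 1 was lowered (8 and 1 over the list alone, camera adjusted p = 0.065). Its largest ratio was of inv1, invertase, which is not a transporter (2.41 ± 0.09). The members isp6, isp5 and aat1 stood at 1.71 ± 0.14, 0.72 ± 0.25 and −0.90 ± 0.14. Of 10 phosphate and thiamine genes, 4 were raised and 2 lowered (4 and 3 over the list alone, camera adjusted p = 0.641), with pho1, an acid phosphatase, at 0.96 ± 0.28, tgp1 at 0.72 ± 0.15, pho84 at 0.67 ± 0.35 and pho4 at −0.66 ± 0.11. With median centring none of these 4 passed, at 0.87, 0.78, 0.52 and −0.83. Of 8 cell separation genes 1 was lowered, eng1 (−0.54 ± 0.20), and none raised (1 lowered over the list alone, camera adjusted p = 0.0518). The ratios of adg1 (−0.32 ± 0.22) and agn1 (−0.29 ± 0.06) did not pass, but both passed without background correction, with processed signals, with scale normalization and with the deposited ratios (adjusted p from 0.0239 to 0.0469). The list passed with an offset of 16 (adjusted p = 0.0492), and eng1, at −0.57, did not pass with median centring (adjusted p = 0.192). Of the 4 strain markers tested, 1 was lowered (3 over the list alone, camera adjusted p = 0.0561). By camera with a preset correlation, 4 of the 19 lists passed upward, Tf2 among them, and 3 downward. With an estimated correlation 0 passed, and the lowest adjusted p was 0.646. That form of the test rests on 1 residual degree of freedom, so hardly any list could pass and it says little. For the fatty acid list the estimated correlation was −0.091, below the preset 0.01, yet the unadjusted camera p went from 5.51e-09 to 0.103. For the other lists that passed, the estimates lay above the preset. They were 0.029 for ribosomal proteins, 0.16 for glycerophospholipids, 0.2 for G1/S and histones, 0.24 for core stress, 0.75 for iron and 1 for Tf2. The preset form may therefore give these lists too small a p, although the estimates too rest on 1 residual degree of freedom. Lists near the threshold passed under single alternatives. Mating and meiosis passed with an offset of 16 (adjusted p = 0.0492) and with processed signals (0.0397). The nitrogen and amino acid transport list passed with the deposited ratios (adjusted p = 0.0453) and separate channels (0.0358). ER chaperones passed with the deposited ratios (adjusted p = 0.0451), and oxygen-requiring enzymes (0.0305) and strain markers (0.0276) with median centring.

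**Figure D3:**
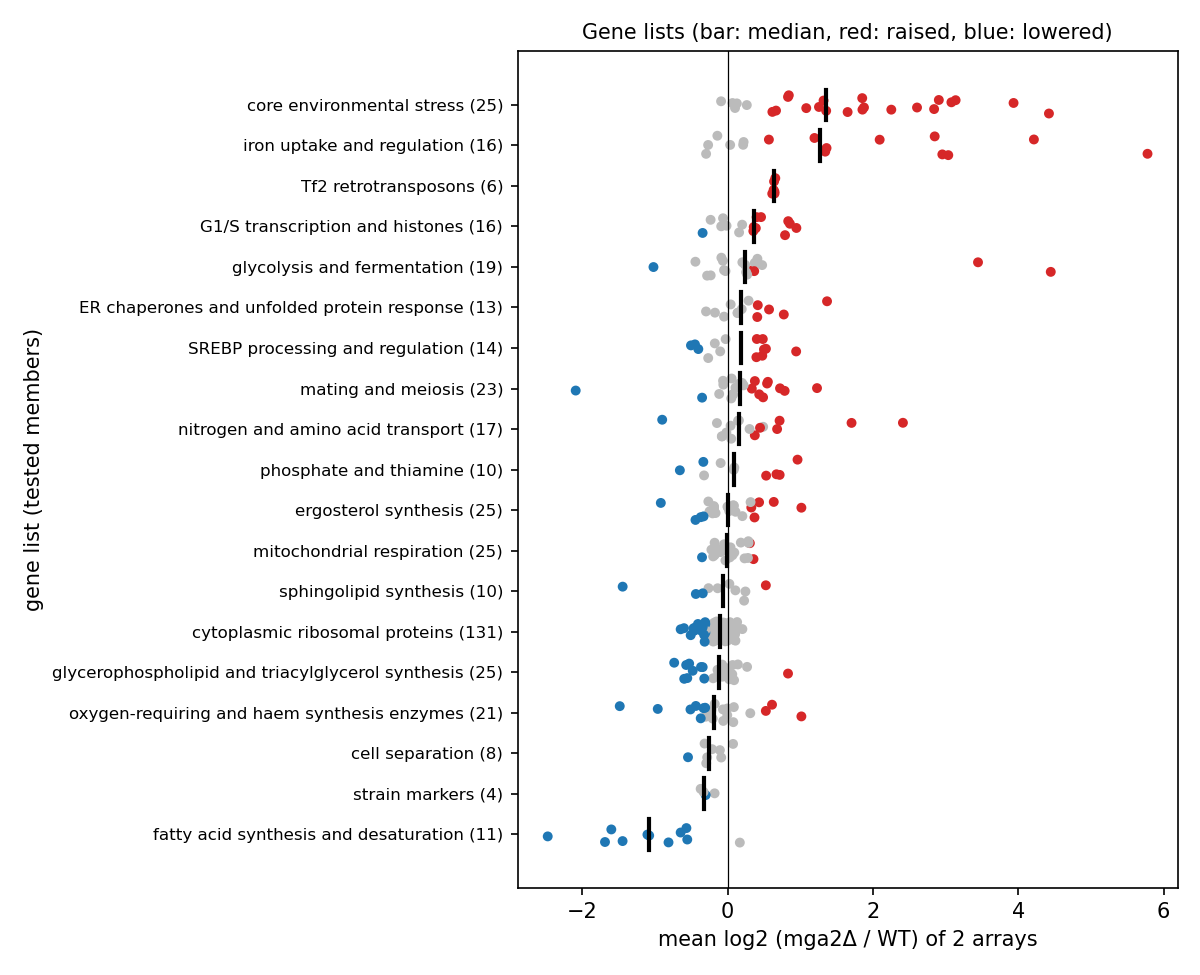
Mean log2 ratio of mga2Δ over WT on 2 arrays (x axis) for each tested member of the 19 gene lists (y axis), with red points raised, blue points lowered, grey points not past the threshold and a bar at the list median. The medians run from −1.08 for fatty acid synthesis to 1.36 for core stress genes.

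Spike-in RNAs, added at set ratios before labelling, gave a check on the ratios. Observed against expected log ratios had slopes of 0.952 and 0.945, per the file headers. After normalization the 10 spike-in probes correlated between arrays with r of 0.997, across probes. All 10 lay below the genes in mga2Δ over WT, with a mean of −0.187 ± 0.075 (SD over 10 probes) and a range from −0.292 to −0.048.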

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

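Median centring, without the intensity-dependent dye correction, lowered the correlation of the arrays to 0.695 and the genes called to 172, all 172 of them among the 1456. Lowering the prior degrees of freedom from 5.62 to 2.81, chosen after seeing the data, gave 669 calls, and the 1.5-fold threshold 427 genes in place of 205, as a looser threshold must. With an estimated correlation 0 lists passed in place of 7, where the test had only 1 residual degree of freedom and hardly any list could pass. Under the other alternatives, counts of calls ran from 1432 to 2027, 2-fold counts from 196 to 253 (184 with median centring), of which 18 to 43 were lowered, and lists passing from 7 to 9. Each array alone had between 233 and 274 genes at 2-fold. The share of rises among calls, 62.8%, was 84.9% with median centring, 52.2% with processed signals, 39.7% with the deposited ratios, 73.7% with 2.81 prior degrees of freedom and 90.4% with spike-in centring, which raised the median of all genes to 0.19 (−0.10 with the deposited ratios). Of 826 values of named genes with a test, 735 kept direction and side of the threshold, 64 lost the call (50 of them with median centring), 26 gained it, and 1 turned: cnx1, at −0.069 with median centring. The cause was not tested. Taking the brightest probe per gene gave nothing, since each gene had 1 probe. No further paired analysis was run, because each array's ratio already sets 1 mga2Δ RNA against 1 WT RNA of the same pair. Signal over background limited few genes: 93 were not tested.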

Other observations

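The tests of the spike-in slope, of spike-in amounts and of matched sets of genes were chosen after the result was seen, and the groups of genes described next were picked after seeing their values. Genes near chromosome ends were raised more often than others. Of 223 tested genes among the 40 outermost probes of each end of the 3 chromosomes, by gene order in assembly ASM294v3, 77 were raised (34.5%), against 832 of 4716 elsewhere (17.6%, two-sided Fisher's exact p = 4.58e-09, odds ratio 2.46). Lowered genes numbered 24 there and 508 elsewhere (Fisher's exact p = 1). Neighbouring genes are not independent, so this p is too small. Among other single genes outside the lists, lowered ones included bio2, biotin synthase (−1.55 ± 0.35, limma adjusted p = 0.000327), and the triacylglycerol lipase gene ptl3 (−0.54 on both arrays, limma adjusted p = 0.00576).

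The 10 raised iron genes differed between the arrays by a median of 1.21, above all of 10000 random sets of 10 from the other 905 raised genes (highest 0.67), and all 10 were higher on array 2. The pattern was noticed in these genes first, and iron genes move together, so they are not 10 independent draws and such sets only describe its size. Larger ratios vary more, but the 73 other genes raised at least 4-fold differed by a median of 0.56, against 1.71 for the 6 such iron genes. Ratio compression on array 1 was argued against by slopes of array 2 on array 1. The slope was 1.63 for the iron genes, through the origin, and 0.97 for the spike-in probes, after centring, a gap of 0.66. The 73 other genes raised at least 4-fold had a slope of 1.14 through the origin. Spike-in probes were not matched to the iron genes on signal, so compression at low WT signal was not tested this way. A WT signal near background as the whole cause was examined in 2 ways. The 1 raised iron gene with WT signal above the median on both arrays differed by 1.07, above the 90th percentile of other raised genes (0.54). By the bounds set beforehand this spoke against the cause, but it rests on 1 gene and other raised genes not matched to it. The median of all 10 lay 0.59 above the 95th percentile (0.62) of 10000 sets of other raised genes matched on WT signal and ratio. The matched genes were slightly brighter in WT (median log2 signal 8.07 against 7.60). These sets draw genes independently, whereas iron genes move together, so they too only describe the size of the difference. Neither comparison can exclude a WT signal near background. Array and dye orientation go together, since mga2Δ carried Cy5 on array 1 and Cy3 on array 2. A dye effect on these genes therefore cannot be told apart from a difference between the replicate cultures, such as in iron state. Neither was tested.

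Spike-in probes lay below the genes by −0.187 on average, which would raise every ratio if the spike-ins were equal in amount. Unequal spike-in amounts may account for it. The shift from the file headers was −0.142 on array 1 and −0.410 on array 2, of the same sign but 0.27 apart. A constant dye offset of the spike-ins would enter the arrays with opposite signs, so this gap alone does not speak for uneven spiking. With 2 pairs of RNAs, uneven spiking cannot be separated from more RNA of other genes in mga2Δ.

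The gene next to mga2, gid5, was raised (1.07 ± 0.02, limma adjusted p = 0.000292), whereas pot1 on the other side stood at 0.14 ± 0.13 (adjusted p = 0.323) and bgl2, farther along beyond pot1, was raised (1.35 ± 0.13, adjusted p = 0.000147). An effect of the deletion on its neighbour could account for it. The 7 other genes of the GID ubiquitin ligase family had a median of 0.48, between the bounds set beforehand, with 6 raised and a range from 0.00 to 0.82, so a rise shared by the family stays open beside a local effect.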
